A study of Mus musculus with 2 samples.

How the data were processed

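RNA-seq of mouse heart at embryonic day 15.5 was analysed from 2 libraries of 1 group. Per the labels, each library came from a separate pool of hearts of strain B6NCrl with both sexes mixed, 78 embryos for replicate 1 and 62 embryos for replicate 2. Per the labels' protocols, RNA was extracted with the mirVana kit, 10 ng of RNA longer than 200 nt entered each library, spike-in RNA was added, and the manual of the SMARTer Ultra Low kit is linked. The labels call the molecule total RNA, while that kit primes with oligo(dT); which of these holds for RNAs without a poly(A) tail is not given in the sources used here. Both libraries hold pooled animals, so the spread between them is a spread between pools and not between single embryos.

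Per the file headers, the authors quantified genes and transcripts on mm10 with the GENCODE M4 annotation from an alignment to the transcriptome. The aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, not normalized, with reads that fit several genes shared out between them. The deposited TPM divide these counts by effective length and scale the sum over all features, spike-ins included, to the same total in each library. A deposited posterior mean TPM stands beside each TPM. In the transcript files the authors' deposited percent gives the share of a gene's TPM in each transcript. Whether the counting used strand is not given in the sources used here, so genes that overlap an antisense partner (Xist and Tsix, for example) are uncertain, as are near-identical paralogs and pseudogenes.

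The 43346 Ensembl genes of the files were matched by stable identifier to GENCODE M21, which is on the same build, for symbols, biotypes and positions. Of these, 42462 matched. The 884 unmatched genes held 0.153% of the gene counts of replicate 1 and 0.169% of those of replicate 2. The files also hold 26248 short features with numeric identifiers and 97 spike-in sequences. These entered neither the tests nor the library sizes of the tests. Total expected counts were 41883313 in replicate 1 and 39697992 in replicate 2. For a transcript with an effective length of 1 kilobase, a single read was worth 0.0308 TPM in replicate 1 and 0.0345 TPM in replicate 2. Intervals on shares are 95% Wilson intervals, and those on ratios of 2 counts are exact. A count of 0 is given with a floor of 3 counts per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

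With 1 group there was no contrast between conditions, and an exact sign-flip test over 2 libraries cannot go below p = 0.5. Before the data were examined, 44 pairs of related genes, 35 gene lists (19 for processes and 16 for cell types) and 25 genes for transcript use were fixed. Of the 518 genes in the lists, 5 had no match by symbol and were left out. Pairs were compared inside the libraries on log2((TPM + 0.1)/(TPM + 0.1)) with limma 3.58.1 (R 4.3.3), an intercept-only fit with moderated variances, two-sided, with Benjamini-Hochberg adjustment over the pairs and a threshold of 0.05. The SE given for a pair is limma's moderated SE, which draws on the spread of all 44 pairs. It can be smaller or larger than the pair's own spread over the 2 libraries. Fold changes on that scale understate the ratio when a gene is low. List levels were the median over members of the mean log2(TPM + 0.1), placed among 10000 random lists of protein-coding genes of the same size. For the comparison of the 2 libraries, log2 ratios of counts were scaled by edgeR's TMM factor (edgeR 4.0.16, expected counts rounded to whole numbers), and the median of each list was placed among 10000 random lists matched on mean expression in 20 bins, over genes with at least 10 counts in both libraries. A list was called apart outside percentiles 2.5 to 97.5. That is a description of these libraries and carries no p-value. The spread was estimated as edgeR's common biological coefficient of variation after its expression filter.

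The text names, in each list, the members with the highest and lowest mean TPM and those that a pair needs. Outside the lists it names the 20 nuclear genes with the highest mean TPM and the 10 genes farthest apart in each direction between the libraries, among those with at least 100 counts in the higher library and a mean of at least 2 TPM. Other members were chosen after their values were seen. Some genes that this rule takes are not reported here.

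Each statistic was tested on simulated data. For the pairs, 20 simulated sets of 44 pairs with the pooled spread gave calls for 2.87% of pairs with no difference, 21.8% at a log2 ratio of 0.5, 65.3% at 1 and 96.7% at 2. Every simulated pair had the same spread, while limma's fit to the real pairs let it differ (7.15 prior degrees of freedom). These rates may therefore not hold for the real pairs. For the lists, 10 simulated pairs of libraries over 17029 genes placed 80.0% of lists changed by a log2 of 0.5 above percentile 97.5, and 3.31% of unchanged lists outside the range. For the spread, counts of 16938 genes simulated with a coefficient of 0.2 and a set of changed genes gave 0.223. Alternatives covered the pseudocount, the posterior mean TPM, the length normalization, the filters, DESeq2 1.42.0 size factors and dispersions, spike-in and nuclear totals as scale, matching on length, and each replicate alone. Matching on GC content, TPM without hemoglobin genes and pairs without the globin genes were added after seeing the data. The marker lists added after the first comparison took genes with at least 10 counts summed over both libraries, and 10 counts in both was run as a further alternative added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.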

Results

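RNA-seq of hearts from mouse embryos at day 15.5, labelled total RNA and at a stage at which the chambers are septated and the muscle is still growing, was available as 2 libraries from separate pools of embryos. Expected counts assigned to Ensembl genes were 41221435 in replicate 1 and 38457396 in replicate 2. At 1 TPM or more, 14120 genes were detected in replicate 1 and 14967 in replicate 2, and 13823 genes reached that level in both. Of these, 12491 were protein-coding, 384 were processed pseudogenes, 240 were antisense genes and 173 were lincRNA genes. Values are given as mean ± SD of the 2 libraries (n = 2) unless each library is named.

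The 20 most abundant nuclear transcripts included hemoglobin, contractile protein and structural RNA genes and copies of mitochondrial genes. Hemoglobin genes led the ranking, with Hba-a2 at 54148 ± 1133 TPM and Hbb-bs at 26520 ± 2637 TPM, followed by Hba-a1 at 19811 ± 508 TPM and Hbb-bt at 18371 ± 229 TPM. The split within each of these globin pairs is uncertain because the copies are nearly identical. Actc1, the cardiac alpha-actin, followed at 10279 ± 814 TPM, Myl2, the ventricular regulatory myosin light chain, at 7151 ± 1547 TPM, and Tnnt2, cardiac troponin T, at 6881 ± 1126 TPM. The nuclear noncoding RNA Malat1 stood at 6447 ± 1408 TPM and Atp5b, the catalytic subunit of ATP synthase, at 4811 ± 426 TPM. The rest of the leading 20 included Tpm1 (3867 ± 824 TPM), Nppa (3801 ± 832 TPM), Myl3 (3492 ± 337 TPM), Tnnc1 (3487 ± 512 TPM), Gapdh (3292 ± 285 TPM) and Ppia (3232 ± 261 TPM). Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, each stood near 10000 TPM (9961 ± 334 TPM for both) and cannot be separated. Gm28437, Gm28661 and Gm29216, with 11015 ± 988, 4543 ± 856 and 4461 ± 595 TPM, are unprocessed pseudogenes on chromosome 1 of mm10 (Gm28437 at 24613189 to 24613971) that are copies of mitochondrial genes, so their counts are uncertain.

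The muscle programme was expressed in full. All 25 sarcomere genes were at 1 TPM or more in both libraries, with a median of 972 TPM, from Myom2 at 21.6 ± 2.24 TPM up to Actc1. Calcium handling genes (20 of 20, median 53.9 TPM) ranged from Cacna1h, a T-type channel, at 4.97 ± 0.552 TPM to Pln, phospholamban, at 654 ± 177 TPM. Of 23 genes for ion channels and junctions, 20 were detected, with a median of 20.0 TPM. Gja1, which encodes connexin 43, was highest at 328 ± 57.4 TPM and Hcn2 lowest at 0.070 ± 0.014 TPM. All 28 cardiac transcription factors were detected, with a median of 16.1 TPM, from Tbx2 at 3.24 ± 1.54 TPM to Nkx2-5 at 114 ± 10.3 TPM. The 16 atrial genes (median 23.8 TPM, Nppa highest and Cacna1d lowest at 1.62 ± 0.226 TPM) and the 16 ventricular genes (median 54.9 TPM, Myl2 highest and Irx5 lowest at 6.84 ± 0.460 TPM) were detected without exception. Each of these 6 lists stood above the range of random protein-coding lists, as did 21 of the 35 lists in all. Against random lists of detected protein-coding genes 14 lists stayed above. Those that did not were ion channels and junctions (percentile 75.2), cardiac transcription factors (53.4), atrial (84.1), nuclear long noncoding RNA (69.4), immediate early (51.9), hypoxia (67.0) and epicardial genes (72.6).

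Genes of energy metabolism were at similarly high levels. Glycolysis genes (21 of 21) had a median of 451 TPM, with Gapdh highest and the brain aldolase Aldoc lowest at 20.3 ± 4.71 TPM. Fatty acid oxidation genes (27 of 28) had a median of 119 TPM, with Fabp3, the heart fatty acid binding protein, at 1208 ± 311 TPM and Ucp3 at 0.165 ± 0.106 TPM. Nuclear genes of oxidative phosphorylation (29 of 29) had a median of 828 TPM, with Atp5b highest and Cycs lowest at 150 ± 43.0 TPM. The 13 mRNAs of the mitochondrial genome had a median of 2102 TPM (log2 medians of 11.62 in replicate 1 and 10.74 in replicate 2), from mt-Nd4l at 136 ± 45.9 TPM to mt-Atp6 at 10913 ± 2096 TPM. Those of mt-Co3 and its neighbours share reads with the pseudogenes on chromosome 1. Hypoxia genes (17 of 17) ran from Car9 at 1.94 ± 0.049 TPM to Bnip3 at 180 ± 36.2 TPM.

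Proliferation, growth, stress and nuclear noncoding RNA lists were also above random lists of all protein-coding genes. S phase genes (21 of 21) had a median of 49.9 TPM, with Rrm2, a ribonucleotide reductase subunit, highest at 178 ± 9.45 TPM. G2 and M phase genes (24 of 24) had a median of 64.7 TPM, with Ube2c at 313 ± 1.36 TPM and Cenpe at 12.3 ± 0.120 TPM. Imprinted growth genes (16 of 16) had a median of 144 TPM, from Peg10 at 1.67 ± 0.028 TPM to Mest at 1490 ± 269 TPM. Immediate early and heat shock genes (20 of 22) had a median of 16.0 TPM, with Hspb1 at 704 ± 126 TPM and Hspa1b at 0.195 ± 0.078 TPM. Nuclear long noncoding RNAs (14 of 16) had a median of 19.5 TPM, with Malat1 highest and Miat lowest at 0.13 ± 0.057 TPM. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of 4.25 TPM (20 of 23), between Hist1h4a at 0.05 ± 0.071 TPM and Hist1h4d at 147 ± 9.29 TPM. Of 12 nonpolyadenylated small and structural RNAs, 3 were detected. The list does not hold Rn7s1 and Rn7s2, the copies of the signal recognition particle RNA, which each had a mean of 9961 TPM. It therefore does not give the level of structural RNAs as a whole. Rn7sk, the RNA of the 7SK particle, was highest at 185 ± 42.6 TPM, and Rnu1b1, Rnu11, Rnu12, Rny1 and Rny3 had 0 counts. At this depth a count of 0 allows up to 1.57 TPM for Rnu1b1 and up to 34.5 TPM for the short Rny3 in replicate 2. The histone list and the small RNA list lay inside the range of random lists of all protein-coding genes. Against lists of detected ones they were at percentiles 0.02 and 0. The kit whose manual the labels link primes with oligo(dT), so levels of RNAs without a poly(A) tail are uncertain.

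Markers of the cell types of the heart were present throughout. Cardiomyocyte markers (12 of 12) had a median of 748 TPM, with Tnnt2 highest and Ryr2, the ryanodine receptor, lowest at 12.1 ± 0.141 TPM. Fibroblast and valve mesenchyme markers (15 of 15) had a median of 113 TPM, from the transcription factor Twist1 at 2.71 ± 0.007 TPM to the collagen Col3a1 at 1015 ± 178 TPM. Endothelial markers (13 of 13) had a median of 41.0 TPM, with Egfl7 at 147 ± 21.5 TPM and Erg at 5.62 ± 1.67 TPM. Epicardial markers (12 of 12) had a median of 20.8 TPM, with the keratin Krt18 at 104 ± 108 TPM and Bnc1 at 2.99 ± 0.594 TPM. Erythroid genes (11 of 12) had a median of 271 TPM, with Hba-a2 highest and the erythroid factor Klf1 lowest at 2.47 ± 2.22 TPM. Smooth muscle and pericyte markers (12 of 12, median 16.0 TPM) ran from Mylk at 7.16 ± 3.37 TPM to Acta2 at 1051 ± 20.9 TPM. Endocardial and valve endothelial markers (8 of 8, median 13.4 TPM) ran from Hapln1 at 4.29 ± 0.163 TPM to Plvap at 81.5 ± 14.4 TPM. Macrophage and leukocyte markers (13 of 13, median 12.8 TPM) ran from Mrc1 at 3.46 ± 0.488 TPM to Lyz2 at 88.1 ± 26.2 TPM. Megakaryocyte and platelet markers (6 of 6, median 3.80 TPM) were led by Pf4, platelet factor 4, at 34.4 ± 0.290 TPM.

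Lists of markers for tissues outside the heart had medians between 0.199 and 8.72 TPM, with single genes far higher. The highest members were Sftpc for lung epithelium and Trf for liver, given by library below. Brain markers had a median of 0.199 TPM, and 1 of 9 was detected, the glutamate transporter Slc17a7 at 2.44 ± 0.481 TPM. Olig2 had 0 counts in both libraries, which allows up to 0.044 TPM in replicate 2. Skeletal muscle genes had a median of 1.02 TPM (6 of 14), with Ckm, also a gene of cardiac muscle, at 1180 ± 226 TPM and Pax7 at 0 counts. Neural crest, glia and neuron markers had a median of 1.71 TPM (4 of 13), thymus markers 2.20 TPM (4 of 10), lung epithelium markers 3.05 TPM (7 of 9), adipose markers 3.66 TPM (4 of 7, Plin1 at 0 counts and Fabp4 at 208 ± 78.5 TPM) and liver markers 8.72 TPM (6 of 10). The libraries differed in several of these levels. In replicates 1 and 2 the median log2(TPM + 0.1) was -0.46 and 2.86 for thymus, -0.74 and 1.68 for neural crest, glia and neuron, 1.71 and 4.28 for liver, 0.99 and 2.43 for lung epithelium and -2.40 and -1.09 for brain markers. All the lists for tissues outside the heart lay inside the range of random lists in level, with liver at percentile 79.5. So did smooth muscle (95.2), endocardial (87.7), macrophage (91.0) and megakaryocyte markers (55.6). Against random lists of detected protein-coding genes the lists for tissues outside the heart stood far lower. Liver was at percentile 12.6, adipose at 1.24, lung epithelium at 0.18, and thymus, brain, skeletal muscle and neural crest, glia and neuron at 0.

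Pairs of related genes of which the heart switches from a fetal to an adult member were compared inside the libraries. The libraries are of whole hearts, so each ratio mixes all cell types and does not by itself place the muscle cells on that course. Of 13 such pairs, 12 passed the limma test, with the fetal member higher in 9 and the adult member higher in 3. Myh7, the fetal beta-myosin heavy chain (chromosome 14, 54970684 to 54994626), exceeded the neighbouring Myh6 (54941921 to 54966927), with 2437 ± 145 against 736 ± 34.5 TPM. The log2 ratio was 1.73 ± 0.19 (limma's moderated SE, as for all SE of pairs, n = 2, limma adjusted p = 2.59e-05). The hexokinase Hk1 exceeded Hk2 (log2 ratio 2.61), the cytochrome oxidase subunit Cox8a exceeded Cox8b (2.15), the enolase Eno1 exceeded Eno3 (3.88-fold), the glucose transporter Slc2a1 exceeded Slc2a4 (1.65), and the dehydrogenase kinase Pdk1 exceeded Pdk4 (1.65). Ldha exceeded Ldhb (1.03), Cox7a2 exceeded Cox7a1 (0.90) and Cox6a1 exceeded Cox6a2 (0.60, limma adjusted p = 0.0191). The adult member led in the muscle carnitine palmitoyltransferase Cpt1b against Cpt1a (150 ± 16.1 against 24.5 ± 5.15 TPM, log2 ratio of Cpt1a over Cpt1b -2.62 ± 0.21 SE, limma adjusted p = 4.53e-06). It also led in the creatine kinase Ckm against Ckb (-2.18) and in the ADP/ATP carrier Slc25a4 against Slc25a5 (-1.10). The slow skeletal troponin I, Tnni1, stood at 3215 ± 251 TPM and the cardiac Tnni3 at 2611 ± 423 TPM, a log2 ratio of 0.31 ± 0.18 SE that did not pass (limma adjusted p = 0.147). Without length normalization Tnni1/Tnni3 reached 0.88 and passed, and Cox6a1/Cox6a2 fell to 0.36 and no longer did. In the same setting the ratio was 2.20 for Cox7a2/Cox7a1, 2.91 for Cox8a/Cox8b and -2.03 for Cpt1a/Cpt1b.

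**Figure D1:**
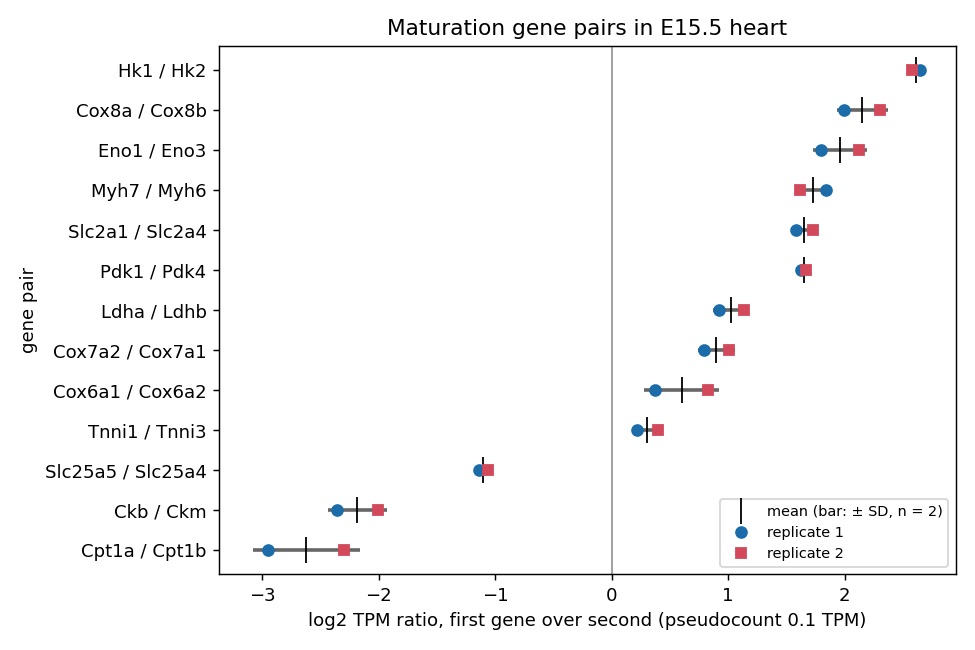
The x axis gives the log2 TPM ratio of the first gene over the second (pseudocount 0.1 TPM) for 13 gene pairs on the y axis, with circles for replicate 1, squares for replicate 2, and the mean with a bar of ± SD. Hk1/Hk2 lies farthest right at 2.61 and Cpt1a/Cpt1b farthest left at -2.62, and Tnni1/Tnni3 at 0.31 did not pass the test.

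Of the other 31 pairs, 25 passed. The SE are again limma's moderated values and can be smaller or larger than a pair's own spread. The SD of the ratio over the 2 libraries reached 0.82 for Atp2a2/Atp2a1 and 0.90 for Hbb-bs/Hbb-y. Cardiac members far exceeded their skeletal muscle relatives, with log2 ratios of 10.75 ± 0.19 (SE) for Tnnt2 over Tnnt3, 9.67 ± 0.19 for Tnnc1 over Tnnc2, 7.76 ± 0.27 for the calcium pump Atp2a2 over Atp2a1, 6.14 ± 0.20 for Ryr2 over Ryr1 and 6.10 ± 0.18 for Actc1 over Acta1. Chamber pairs had the ventricular light chains ahead, with Myl7 over Myl2 at -1.16 and Myl4 over Myl3 at -1.29, while Nppa, the atrial natriuretic peptide, exceeded the adjacent Nppb by a log2 ratio of 4.93. Among regulators, Gata4 exceeded Gata6 (0.90), Tbx5 exceeded Tbx3 (1.51), Mef2a exceeded Mef2c (-1.38 for Mef2c over Mef2a), Hey2 exceeded Hey1 (1.02), Irx4 exceeded Irx3 (1.37), Nr2f2 exceeded Nr2f1 (2.27) and Ccnd2 exceeded Ccnd1 (-0.97 for Ccnd1 over Ccnd2). The growth factor Igf2 exceeded Igf1 (4.89), Vegfb exceeded Vegfa (-4.42 for Vegfa over Vegfb), Bmp4 exceeded Bmp10 (-1.86 for Bmp10 over Bmp4) and Tgfb2 exceeded Tgfb3 (0.81). Channel and junction pairs were led by Gja1 over Gja5 (2.14), Hcn4 over Hcn2 (3.02) and Cacna1c over Cacna1d (4.81). Hcn4/Hcn2 ranged from 1.09 to 4.02 with the pseudocount, and Cacna1c/Cacna1d was 3.15 without length normalization. Most of the TPM of Cacna1c was in a transcript of 954 bases that is not annotated as protein-coding, so the ratio of channel mRNAs is uncertain. Adult-type globins exceeded embryonic ones, with Hbb-bs over Hbb-y at 4.92 ± 0.29 (SE; 5.56 in replicate 1 and 4.29 in replicate 2) and Hba-a1 over Hba-x at 6.46 ± 0.24. The pairs that did not pass were Cacna1g/Cacna1h (0.11), Kcnj3/Kcnj2 (0.13), Pfkm/Pfkl (-0.42), Hand2/Hand1 (-0.25), Mycn/Myc (-0.36) and Col1a1/Col3a1 (-0.34). In all, 37 of 44 pairs passed (limma, adjusted over the list alone, n = 2), each with the same sign in both libraries. Without length normalization Cacna1g/Cacna1h turned to -0.77 and passed, Pfkm/Pfkl passed at -0.80, and Tgfb2/Tgfb3 no longer passed at 0.44. Igf2/Igf1 was 2.81, Ccnd1/Ccnd2 -2.52, Vegfa/Vegfb -3.30, Ryr2/Ryr1 7.37 and Atp2a2/Atp2a1 9.08 in that setting, and Ryr2/Ryr1 was 3.61 and Atp2a2/Atp2a1 6.85 with a pseudocount of 1 TPM.

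The libraries were close across genes. Over the 13823 genes, Pearson's r of log2 TPM was 0.981 and Spearman's rho 0.980, across genes that are not independent replicates. The median absolute log2 ratio was 0.24, 87.5% of genes lay within 1.5-fold and 96.2% within 2-fold. The chi-square per degree of freedom over 19372 genes was 47.1, a value that lies above 1 for any libraries prepared separately. The common biological coefficient of variation was 0.227. The square root of DESeq2's median gene-wise dispersion, on the same scale, gave 0.0761.

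The share of counts in several gene classes differed between the pools. Hemoglobin genes took 4.73% (95% Wilson interval 4.72 to 4.74) of counts in replicate 1 and 4.25% (4.25 to 4.26) in replicate 2. The mitochondrial genome took 3.64% (3.63 to 3.64) and 2.41% (2.41 to 2.42), and spike-ins 1.58% and 3.12%. Over 60 spike-ins with at least 10 counts in both libraries, the median log2 count ratio was 0.99 (SD 0.30 over spike-ins). Protein-coding genes took 93.4% and 92.6% of counts, annotated rRNA genes 2.52e-05% and 3.53e-05%, and the 10 most abundant genes 9.64% and 8.04%. As shares of TPM, hemoglobin genes took 12.2% and 11.8%.

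Compared with replicate 1, markers of thymus, liver, lung epithelium, neurons, brain and macrophages were higher in replicate 2, and sarcomere, cardiomyocyte and oxidative phosphorylation genes were lower. Of 35 lists, 10 stood above the range of random lists of equal abundance and 12 below it, where chance gives 5% of lists. That 5% is for lists of unrelated genes and does not allow for members that vary together. Some lists also share genes (Myh7 and Myl3 are in the sarcomere, ventricular and cardiomyocyte lists), so they are not separate results. The ratios are on the TMM scale, on which the median gene stood at 0.01. Scaling by total gene counts adds 0.15 to each log2 ratio, and scaling by spike-ins shifts each by -0.86, so directions are relative to the median gene. Each library is a single pool, so the difference has no replicate check. List values are medians of the members' ratios, which can differ in direction from the ratio of the list medians, as for ventricular genes.

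Thymus markers were 9.56-fold higher in replicate 2 at the median (7 of 7 measured members above the median gene), with the T cell kinase Lck at 5.67 TPM in replicate 1 and 51.0 TPM in replicate 2. Dntt had 3 counts in each. Liver markers were 6.01-fold higher (10 of 10), with the transferrin gene Trf at 31.5 and 104 TPM and the fibrinogen gene Fgb at 0.27 and 2.27 TPM. Neural crest, glia and neuron markers were 5.14-fold higher (11 of 11), with Stmn2, a neuronal microtubule regulator, at 5.70 and 22.5 TPM and Chat at 0 and 3 counts. Lung epithelium markers were 2.62-fold higher (8 of 8), with the surfactant gene Sftpc at 118 and 276 TPM and Scgb1a1 at 0.25 and 0.37 TPM. Brain markers were 2.27-fold higher over the 4 members with enough counts. Macrophage and leukocyte markers were 1.32-fold higher (13 of 13). Smaller shifts of the same direction were seen for epicardial (1.13-fold, with Krt18 at 28.1 and 180 TPM), imprinted growth (1.13-fold), erythroid (1.12-fold) and S phase genes (1.06-fold). The erythroid list split, with the embryonic globin Hbb-y at 602 and 1264 TPM while the adult-type globins lay below the median gene. With at least 100 counts required, the erythroid list fell to percentile 91.0 and was no longer apart.

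On the other side, nuclear genes of oxidative phosphorylation had a median ratio of 0.714 in replicate 2 over replicate 1 (0 of 29 above the median gene), ventricular genes 0.714, fatty acid oxidation genes 0.733, sarcomere genes 0.753 (0 of 25), cardiomyocyte markers 0.756 and mitochondrial mRNAs 0.656. Part of this was shared by random lists of equal abundance. Their median log2 ratio was -0.18 against -0.49 for oxidative phosphorylation, -0.17 against -0.41 for sarcomere and -0.17 against -0.61 for mitochondrial mRNAs. Calcium handling genes (0.836) and ion channels and junctions (0.836) were lower by less. Adipose genes (0.733 over 4 members, Fabp4 at 264 and 153 TPM), nonpolyadenylated RNAs (0.620 over 3 members, Rn7sk at 215 and 154 TPM), sex-linked genes (0.811) and histone genes (0.906) were lower too. The structural RNAs Rn7s1 and Rn7s2, outside that nonpolyadenylated list, each had a log2 ratio of -0.15. Of the sex-linked genes, the 4 on the Y chromosome lay below the median gene, from Kdm5d at 4.14 and 4.30 TPM to Eif2s3y at 28.9 and 21.7 TPM, while Xist, the X inactivation RNA, stood at 10.1 and 15.1 TPM. The sex-linked list (median level 12.4 TPM) was not apart, at percentile 18.7, when random lists were also matched on GC content. The epicardial list was at the edge of the range under the same matching and no longer apart. Matched on length, the histone list was at percentile 55.6 and the nonpolyadenylated list at percentile 2.88, neither apart.

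The other 13 lists lay inside the range of random lists. Their median log2 ratios were -0.13 for cardiac transcription factors, -0.08 for atrial genes, -0.25 for glycolysis, -0.13 for G2 and M phase, -0.03 for nuclear long noncoding RNAs, -0.06 for immediate early genes and -0.12 for hypoxia genes. Among cell types they were -0.01 for endothelial, -0.20 for endocardial, -0.05 for fibroblast, 0.06 for smooth muscle, -0.18 for megakaryocyte and 0.20 for skeletal muscle markers. Some of these were below the range under other matching, cardiac transcription factors (percentile 0.890) and glycolysis (1.81) on length, and both lists on GC content as well. Endocardial markers were below it on length (1.10) and megakaryocyte markers on GC content (2.20).

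**Figure D2:**
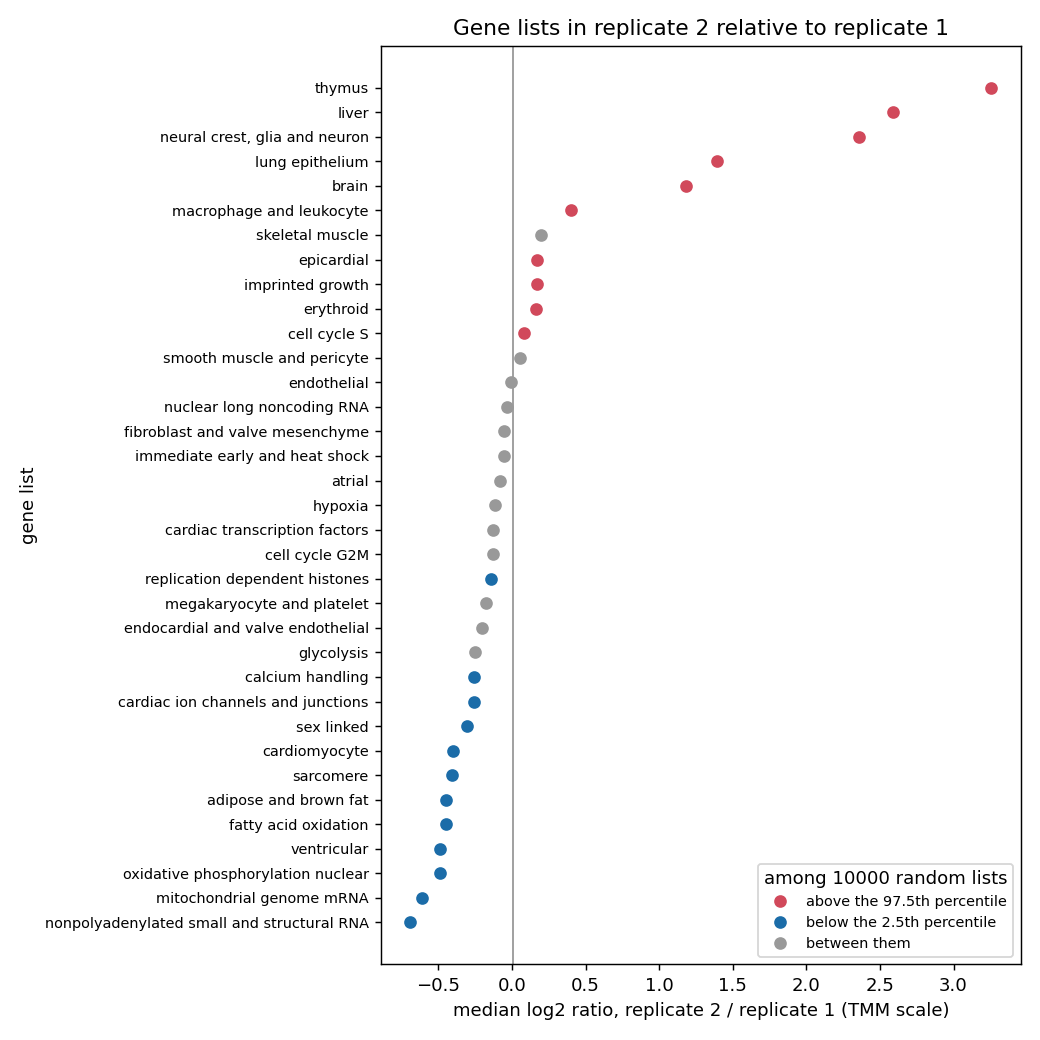
The x axis gives the median log2 ratio of each list's genes in replicate 2 over replicate 1 (TMM scale, 1 library each), and the y axis the 35 lists, with red points above the range of 10000 random lists, blue points below and grey points inside. Thymus lies farthest right at 3.26 and nonpolyadenylated RNA farthest left at -0.69.

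**Figure D3:**
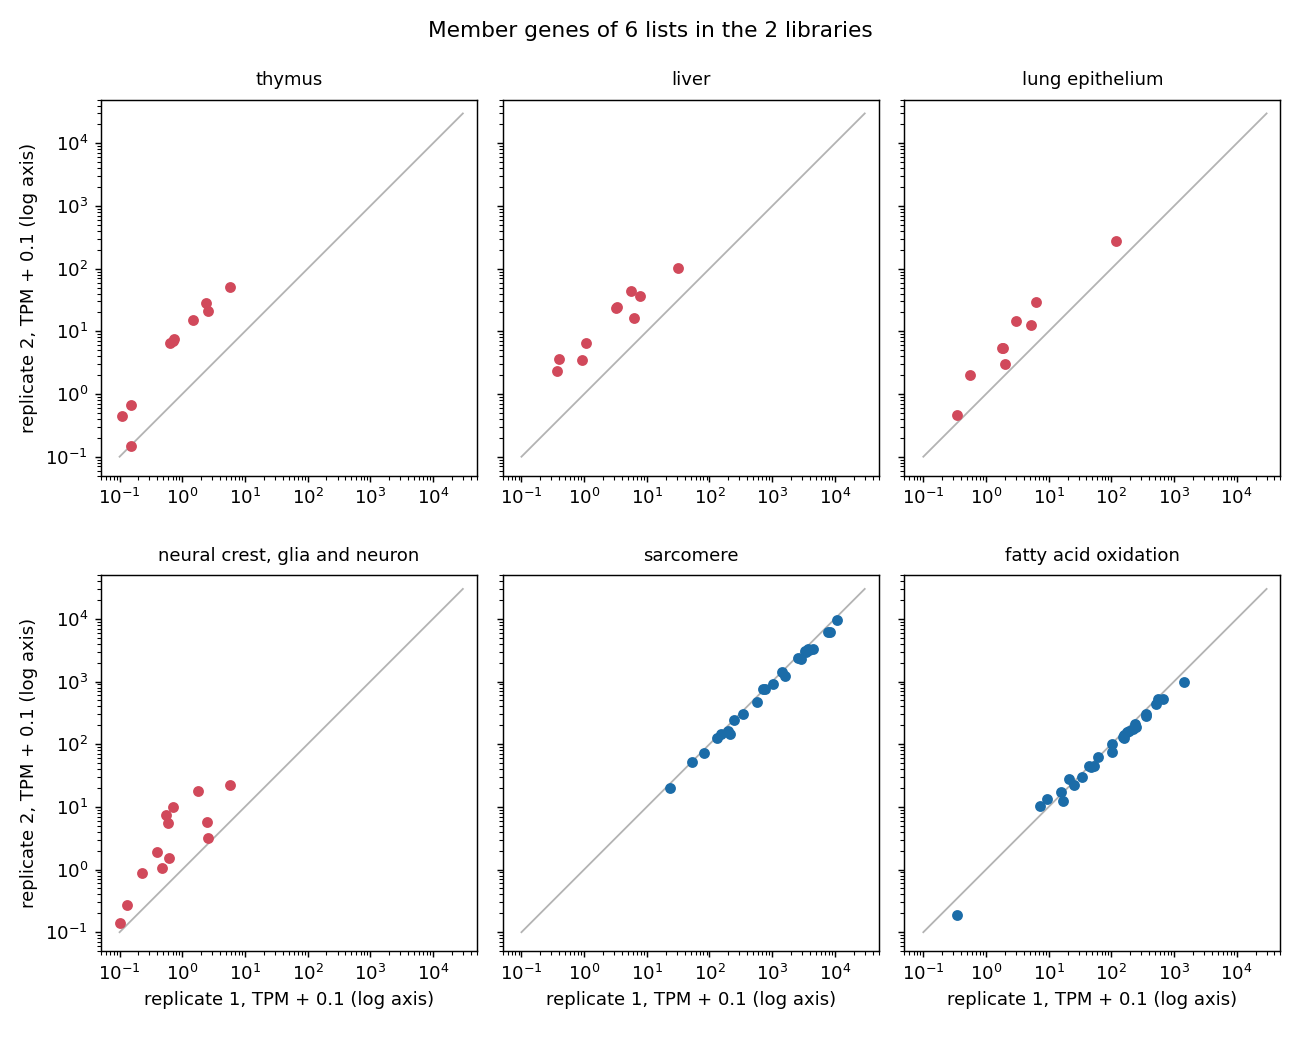
Each point is a gene, with its TPM plus 0.1 in replicate 1 on the x axis and in replicate 2 on the y axis, both log axes, for 6 lists, and the grey line marks equal values. Lck, the highest thymus gene, lies at 5.67 and 51.0 TPM.

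Farthest apart between the libraries on the side of replicate 2 was a gene without a symbol, with 0 counts against 325, at least 105-fold higher against the floor of 3 counts. Next came Pth, parathyroid hormone, with 3 counts in replicate 1 and 131 in replicate 2 (log2 ratio 5.18, exact 95% interval 3.82 to 7.69) and Chga, chromogranin A of neuroendocrine cells, with 18 and 494 counts (4.69, interval 4.05 to 5.49). Bpifa1, an airway secretory gene, followed at 4.28 and Fbp1, a gluconeogenic enzyme, at 4.23. Tgtp2 stood at 3.93, Bcl2l14 at 3.82, Pax1, a factor of the pharyngeal pouches and thymus, at 3.81, Th, the rate-limiting enzyme of catecholamine synthesis, at 3.79, and the peripheral neuron filament Prph at 3.77. Among the 10 genes highest in replicate 1, Gm20431 had 405 counts against 0, at least 140-fold higher against the floor of 3 counts. Gm10240 was at least 67.2-fold and Gm13304 at least 44.8-fold higher by the same measure, Gm20425 had a log2 ratio of -3.16, and these predicted genes are uncertain. The others were Pnliprp1 (-2.35), Gm10925 (-2.01), mt-Co3 (-1.59), Fam221b (-1.52) and Tsix (-1.51). Gm10925 (chromosome 1, 24613974 to 24614651) is a nuclear copy of mitochondrial sequence, and Tsix overlaps Xist on the opposite strand, so both are uncertain. A gene without a symbol, at least 73.8-fold higher, ranked after Gm20431.

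Transcript use was similar in both libraries. Of 9530 genes with several annotated transcripts and at least 1 TPM, 90.3% had the same leading transcript, whose share of the gene's TPM was 69.2% at the median, and 2289 genes (24.0%) had a leading transcript above 90%. Tpm1 was nearly all in Tpm1-205 (93.0 ± 0.495%), Bin1 in Bin1-202 (98.4 ± 0.580%) and Atp2a2 in Atp2a2-202 (89.5 ± 0.820%). Tnnt2 was spread over several transcripts, led by Tnnt2-207 (52.5% and 48.9% in replicates 1 and 2) and Tnnt2-211 (18.3 ± 0.304%). Pyruvate kinase Pkm was 70.8 ± 4.20% in Pkm-202 and 29.2 ± 4.20% in Pkm-201. Actn1 moved from 68.4% in Actn1-201 in replicate 1 to 53.6% in replicate 2. For Vegfa, at 5.32 ± 0.318 TPM, Vegfa-211 led in replicate 1 with 64.7% and Vegfa-201, at 15.2% there, led in replicate 2 with 33.7%. By posterior means these leading shares were 46.75% and 28.9%. The deposited TPM interval of Vegfa-211 was 1.61 to 3.44 in replicate 1 and reached 1.63 in replicate 2, so the change of leading transcript is uncertain. For Fn1, fibronectin, Fn1-202 led in replicate 1 (34.6% against 31.8% for Fn1-201) and Fn1-201 in replicate 2 (38.1% against 26.6%). Fn1-202 is annotated as a retained intron and Fn1-201 as protein-coding. For Ttn and Cacna1c, short transcripts took most of the TPM, Ttn-215 (2159 bases, 77.3 ± 0.283%) against Ttn-201 (81843 bases, 6.20 ± 0.226%) and Cacna1c-218 (954 bases, 80.7 ± 2.34%). Cacna1c-218 is annotated as a processed transcript and not as protein-coding. The leading protein-coding transcript, Cacna1c-207, stood at 5.42 and 5.62 TPM in replicates 1 and 2. Other genes fixed for this purpose were led by Mef2c-203 (65.4 ± 1.91%), Mef2a-208 (54.0 ± 2.41%), Ldb3-203 (57.0 ± 2.34%), Camk2d-202 (43.1 ± 1.35%) and Pdlim5-205 (66.7 ± 3.85%). Such shares are estimates from reads that fit several transcripts.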

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

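The short features with numeric identifiers, which enter no comparison above, held 42.7 expected counts in replicate 1 and 64.0 in replicate 2. Both totals are above the 3 counts that a count of 0 allows. That floor is for a single feature and the totals are sums over 26248, so passing it says nothing on any 1 feature. The totals amount to 0.000102% and 0.000161% of the counts. No explanation was tested for them.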

How the results depend on the processing

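Matching on GC content, removing hemoglobin genes from TPM, removing the globin pairs and the count filter on the added marker lists were chosen after seeing the data. The number of pairs called stayed between 36 and 38 over all alternatives run against 37. The 36 came from leaving out the 2 globin pairs, both called, with the variances and the adjustment done again. Each replicate alone gives the sign of a pair with no test, and the called pairs kept their sign in both. Without length normalization Cacna1g/Cacna1h reversed to -0.77, Tnni1/Tnni3 and Pfkm/Pfkl gained the call, and Cox6a1/Cox6a2 and Tgfb2/Tgfb3 lost it. Dropping the length term changes each pair by the ratio of the lengths. As shares of TPM in place of counts, spike-ins took 4.63%, the mitochondrial genome 4.98%, hemoglobin genes 12.0%, the 10 most abundant genes 17.9% and the 100 most abundant genes 37.8%. TPM weighs short transcripts more by construction. The spread between libraries was 0.226 with DESeq2 size factors and 0.259 with no filter, and 0.0761 as the square root of DESeq2's median gene-wise dispersion, which is a median over genes, while edgeR's value is fitted to all genes at once. Genes at the detection level in both libraries numbered 9991 at 5 TPM, 15422 at 0.5 TPM, 14029 with TPM over nuclear genes and 16655 with posterior mean TPM. Lists with a high level numbered 14 when random lists held detected genes only and 20 or 21 otherwise. For the lists apart between libraries, a single scale factor cannot change a percentile, so the scaling alternatives say nothing about stability. At 100 counts 18 of 32 lists were apart, all among the 22, and with matching on length or GC content 23 were apart, of which 20 were among the 22 in each case. The same leading transcript was found for 89.9% of genes with posterior means and 92.6% at 10 TPM. With 10 counts required in both libraries, 5 of 5 added lists near the heart and 1 of 6 far from it reached a log2 of 1, as before. The thyroid and parathyroid list, then of 2 genes, fell from percentile 98.2 to 95.25, inside the range of random lists. The kidney list, also of 2 genes, moved from 96.7 to 97.51, just above it. Depth limits the low markers: the 6 lists for organs far from the heart had between 2 and 6 genes with enough counts.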

Other observations

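Second marker lists for thymus, liver, lung and neurons, written after the first lists had been compared and before their own values were seen, were higher in replicate 2 as well. A second thymus list was 5.55-fold higher in replicate 2 at the median (12 of 12 genes), with the thymic epithelial protease Prss16 at 7.85 and 92.0 TPM, Cd3g at 4.57 and 52.9 TPM and the thymic chemokine Ccl25 at 9.45 and 47.2 TPM. A second liver list was 3.73-fold higher (12 of 12), with Ambp at 1.24 and 6.79 TPM. A second list for lung and airway epithelium was 3.17-fold higher (12 of 12 measured), with Krt15 at 3.49 and 16.6 TPM. A second list for sympathetic neurons was 5.84-fold higher (11 of 12), with the filament gene Nefm at 1.33 and 10.3 TPM, while Uchl1, also high in replicate 1, stood at 74.1 and 78.8 TPM. The thyroid and parathyroid list, prompted by Pth and Pax1 among the genes farthest apart, had 3 measured genes, Casr with 2 and 9 counts, Pax9 at 7.71-fold, and Tg, the thyroglobulin gene, with 140 and 148 counts at 1.02-fold. The genes named here were chosen after their values were seen. None of these genes is in another list. In replicate 1, 7 of the 12 second thymus genes, 4 of the 12 liver genes, 7 of the 13 lung and airway genes and 5 of the 12 neuronal genes were at 1 TPM or more.

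In the paragraphs that follow, the tests of low counts, of well-counted genes of organs far from the heart, of gene length and GC content for the muscle and energy genes, of a smaller cardiomyocyte share, of Xist and Tsix reads and of GC content for the Y genes were chosen after the result was seen. The design has 1 group and names no biological difference between the pools, so none that it names was tested.

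Thymus, liver, lung and neuronal marker genes were higher in replicate 2. Low counts do not account for it, since the 15 genes of the 4 second lists with at least 100 counts in both libraries had a median log2 ratio of 2.15 (14 of 15 higher), against -0.14 to 0.19 for random lists of equal abundance. Reads from libraries of many other organs would raise organs far from the heart as well, and 1 of 6 such lists (kidney 1.73, intestine 0.84, pancreas -0.59, eye -0.45, gonad 0.01, forebrain 0.95) reached a log2 of 1, as did the brain list fixed earlier at 1.18. The pancreas list lay below the range of random lists, at percentile 0.62 over 6 genes. Over its 3 genes with 10 counts in both libraries it was inside, at 9.865. At least 3 of the 6 lists had been asked to reach a log2 of 1, and fewer did, but they rest on 2 to 6 counted genes each. With at least 100 counts required in both libraries, 5 genes from 5 organs remained: Lgals4, Cpa1, Pmel, Inha and Cdh16. Their median was -0.24 and their highest value 0.34. That filter keeps genes already well counted in replicate 1 and drops low ones, among them Six2 with 11 and 104 counts. It therefore cannot decide the question, and reads from many or from a few other libraries stay open. Tissue next to the heart in the replicate 2 pool stays open as well. All 5 second lists near the heart reached a log2 of 1, but 4 of them are of tissues already seen to be higher. The other, thyroid and parathyroid, was prompted by Pth and Pax1, genes already seen to be higher. RNA of the same tissues from any other source would give the same.

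Sarcomere, fatty acid oxidation and oxidative phosphorylation genes were lower in replicate 2. Over 81 genes the median log2 ratio was -0.45, against -0.22 to -0.09 for random lists of equal abundance. With a trend on gene length removed the median was -0.40 and with a trend on GC content removed it was -0.45, both below the lowest 2.5% of random lists, so neither trend accounts for the whole. A smaller share of all cardiomyocytes would raise the other cell types of the heart together, and 2 of 6 such lists (epicardial at percentile 98.7, macrophage at 100) were above the range of random lists. Both hold genes that are not specific to the heart, such as the keratin Krt18 and the leukocyte gene Ptprc. Their rise therefore cannot separate a smaller cardiomyocyte share from a gain of neighbouring tissues. Endothelial stood at 77.9, fibroblast at 82.2, smooth muscle at 93.8 and endocardial at 3.94, none outside the range, though with matching on length endocardial was at 1.10 and with matching on GC content epicardial no longer passed. A smaller share and a gain of neighbouring tissues alone, which may lower heart genes relative to the rest, both stay open. Other differences between the pools of embryos were not tested for these genes.

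Xist was higher and the Y-linked genes lower in replicate 2, by a log2 ratio of 0.37 and a median of -0.30. Reads moved between the overlapping Xist and Tsix stay open for part of the Xist rise. Xist had 5758 and 7731 counts in replicates 1 and 2, and Tsix 826 and 299. Among 844 single genes of equal abundance Xist stood at percentile 98.2. Moved reads would leave the sum of both unchanged, and it still had a log2 ratio of 0.24. That sum was at percentile 93.7, inside the range. GC content bias may account for the Y genes, which have a median GC content of 37.5% against 50.4% for all genes: with the trend removed their median was -0.04, at percentile 28.0 of random lists. More female embryos in the replicate 2 pool cannot be told apart from this, since the 4 X-linked genes that escape inactivation stood at percentile 91.2, inside the random range.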
